A study of Mus musculus with 9 samples.

How the data were processed

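The data are log ratios from dual-channel expression arrays of castrated against sham-operated C57BL/6 mice. Total RNA was reverse transcribed into aminoallyl cDNA and labelled with Cy3 or Cy5, so that each array holds a castrated and a sham-operated mouse. There were 3 groups of 3 arrays: bone and bone marrow of young mice (17 weeks) and specimens labelled bone marrow of old mice (59 weeks), all from animals castrated or sham-operated at 7 weeks. Per the design text each replicate is a separate pair of mice. The castrated mouse was in the Cy5 channel on 6 arrays and in the Cy3 channel on 3 arrays, 1 per group (young bone replicate 3, young marrow replicate 2, old replicate 2), called swapped arrays here. The design text speaks of separating the marrow only where it names the young mice, and whether the old specimens also hold bone is left open.

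The deposited values are log ratios, which were read as log2 ratios; the log base, the direction of the ratio, the background treatment and the normalization were not given in the sources used here, and natural logs were not excluded. The deposited file held 11552 features on 9 arrays, with 8290 to 10995 values per array. The mean of each array lay within 0.0021 of 0, the medians lay between -0.11 and 0.01, and no column duplicated another. The SD across features was 0.192 to 0.294 on 8 arrays and 0.455 on old replicate 1, whose median over the features tested was -0.12. No scaling was added in the main analysis, and intensities were not used here, so that signal over background is unknown and the number of arrays limits the precision.

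Because the direction of the ratio is not stated, every comparison was run under 2 readings. Under the channel reading the value is Cy5 over Cy3 and the swapped arrays were multiplied by -1. Under the castrated-over-sham reading the ratio had already been turned to castrated over sham, and no array was changed. On the 6 unswapped arrays the readings are identical. The choice was made by a rule fixed before the data were examined, as were the gene lists, the tests and the named genes: per group, the mean Pearson r across features of the swapped array with its group mates, minus that with the unswapped arrays of the other groups. Across features, which are not independent replicates, this difference was -0.13 for young bone, 0.46 for young marrow and 0.08 for the old group. The rule asked for all 3 groups to lie above 0, so the channel reading became the main one. Counts are reported under both readings, while many named genes are given under a single one. The labels point the other way, since they describe all 9 arrays as castrated against sham. On that basis the castrated-over-sham reading is the likely one. The dye term, fitted with limma, held 231 features under the channel reading against 0 under the castrated-over-sham reading (583 at an unadjusted p under 0.05, with 444 expected by chance). Dye and castration change places between the readings, so these counts mirror those of the average and do not tell a dye effect from a castration effect. A direction is stated for castrated over sham only where the sign was the same under both readings and in the mean of the unswapped arrays. Elsewhere, and for named genes at 0.00 under a reading, the sign of the deposited ratio is given. The rule asks for the same sign and not the same size. Channel values of genes that meet it can lie near 0, such as 0.01 for Cecr2 in young bone against 0.90. Rose and fell thus do not mean a change that holds under the channel reading, where 0 features passed. The sign of a value near 0 can turn by noise alone, as for Scd1 in young bone, which fails the rule at -0.03 against 0.85. Rose and fell are therefore not better supported than a deposited ratio above or below 0 on every array. Values given under the channel reading carry the sign of that reading. Members of a list counted as up or down are past the threshold under the reading named, with that sign.

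Features were tested if they had a value on at least 2 arrays of every group and on at least 1 swapped array, which left 8885 features, 7544 of them with a value on all 9 arrays. A limma fit of all 9 arrays held 1 coefficient per group and a common dye term, with 5 residual degrees of freedom before moderation. Standard errors of the contrasts were computed exactly for each pattern of missing values, since the limma routine approximates them there; this choice was made after the data were seen. P values were adjusted by Benjamini-Hochberg over all features of a comparison, with a threshold of 0.05. The comparisons were the castration effect in young bone, in young marrow, in the old group and averaged over the 3 groups, and the differences between each pair of groups. Numbers printed as SE are standard errors of the fit, and numbers printed as SD are across arrays.

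Feature names came from the platform annotation, with symbols updated by gene ID from the mouse reference table. Of the 11552 features, 8050 mapped to a single gene, 672 to several genes and 2830 to no gene; features of several genes or none were counted but not named, and the symbols of 170 single-gene features were not in the reference. The tested features with a name numbered 6490, for 4775 genes. Named genes are, per castration comparison, the 10 largest rises and 10 largest falls past the threshold with the same sign on every array of the groups concerned. Where fewer than 5 features passed, the 10 with the smallest unadjusted p are named as values. Also named are the 4 members with the smallest p of each gene list past the threshold, the 3 with the smallest p of 5 lists (osteoblast, osteoclast, adipocyte, B lymphocyte, sex steroid), and single genes fixed in advance where measured, among them Igf1, Tnfsf11 and Tnfrsf11b.

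The 21 gene lists covered osteoblast and bone matrix, osteoclast, RANKL, OPG and Wnt signalling, BMP, TGF-beta and IGF signalling, cartilage, adipocyte and lipid storage, B lymphocyte lineage, T and NK lymphocyte, granulocyte, monocyte, macrophage and dendritic, erythroid, megakaryocyte and platelet, endothelial, skeletal muscle, cell cycle, sex steroid receptors, metabolism and response, interferon response, inflammatory cytokines and receptors, oxidative phosphorylation, heat shock and immediate early response, and cytosolic ribosome. A list needed 5 measured members, which left 19; cartilage, with 2 measured, and T and NK lymphocyte, with 3 measured, were not tested. No gene was in more than 1 list. Lists were tested with the cameraPR function of limma, the form of camera that takes a statistic per gene, since camera itself takes no missing values. The statistic was the moderated t of the mean over the features of a gene, the preset correlation was 0.01, and p values were adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run on the genes with a value on all 9 arrays; fry asks another question, whether a list differs from no change and not from the other genes.

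The alternatives were the other reading, no dye term, the unswapped arrays alone, array medians set to 0 with or without equal spread, complete features, array weights, trend and robust moderation, values per gene, each group or pair of groups fitted alone, a block for the replicate number, and each array left out in turn. The trend was fitted against the mean log ratio of a feature, as turned for the reading, and not against intensity. The code was tested on simulated data with 8885 features, of which 200 carried a change and 200 a dye effect. When the simulated ratios were analysed under their own reading, a change of 1 log2 was recovered for 99% to 100% of features and of 0.5 log2 for 54% to 76% in a single group and 99% to 100% in the average, and no recovered change had the wrong sign. When they were analysed under the other reading, at most 4 of 100 changed features were recovered. A simulated list of 12 genes shifted by 0.3 log2 was recovered in 100% of 50 simulations, and 3 of 900 unshifted lists were called. The simulated genes were independent, so this does not show how often lists of correlated genes are called in error. In all simulations the spread was the same on every array and came from the fit under the castrated-over-sham reading. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.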

Results

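Gene expression was compared between castrated and sham-operated mice in young bone, young bone marrow and old specimens labelled bone marrow. Each group had 3 arrays, with a separate pair of mice on each array of a group. Whether young bone and young marrow came from the same pairs is not stated. Between 8290 and 10995 features per array carried a value, and 8885 were tested; the number of arrays limits the precision. All values are log2 ratios as read here. The direction of the deposited ratio is not stated, so each comparison was read in both possible ways. The channel reading takes the ratio as Cy5 over Cy3 and is the main one by the rule fixed in advance. The castrated-over-sham reading takes it as already turned, and is the likely one from the labels. Of the 7544 features with a value on every array, 314 (4.16%) kept a single deposited sign on all 9 arrays. By chance 0.39% would be expected if the arrays were independent. Of these, 138 were positive and 176 negative.

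The first question was which genes responded to castration in common across tissues and ages. The median of the B lymphocyte lineage genes stood above 0 and that of the granulocyte genes below 0 on all 9 arrays. Under the castrated-over-sham reading, Vpreb3, a protein of early B cells that binds immunoglobulin heavy chains, rose by 1.09 (SE 0.06, n = 9, limma adjusted p = 1.6e-05, positive on 9 of 9 arrays). Bach2, a transcription factor of B cells, rose by 1.13, and Pou2af1, a B cell coactivator, rose by 0.96. Igfbp5, which binds insulin-like growth factors, rose by 1.03, and Scd1, which desaturates fatty acids, rose by 0.95. Pilra, an inhibitory receptor of myeloid cells, fell by 0.55 (SE 0.08, limma adjusted p = 0.0048, below 0 on 9 of 9 arrays). Under the channel reading Vpreb3 stood at 0.14, Pou2af1 at 0.03 and Scd1 at 0.13, and 0 features passed by limma.

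For the next genes the sign differed between the readings or was 0.00 under the channel reading, so only the deposited ratio is given. It was above 0 on 9 of 9 arrays for Fcrla, an Fc receptor-like protein of B cells (1.08), and Cd79b, a signalling subunit of the B cell receptor (0.95). The same held for the striatin Strn3 (0.98), for Pafah1b3 (0.91) and for the second feature of Igfbp5 (0.96). It was below 0 on 9 of 9 arrays for Il1r2, the decoy receptor of interleukin-1 (-0.62), the lysozyme Lyz2 (-0.62) and the mitochondrial arginase Arg2 (-0.58). Anxa1, the annexin A1 of granulocytes (-0.55), Ctsg, a protease of neutrophil granules (-0.55 in both features), Lpcat2 (-0.56) and Cep19 (-0.56) were also below 0 on 9 of 9 arrays, and Dmxl2 (-0.56) on 8 of 8. All of these passed the limma threshold under the castrated-over-sham reading, with adjusted p values up to 0.015. A second feature of Strn3 did not follow the named one: it gave 0.26, 0.05 and 0.11 in young bone, young marrow and the old group, against 0.99, 0.55 and 1.42.

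By list, 8 of the 12 measured B lymphocyte genes were up over all genes under the castrated-over-sham reading, and 9 were up adjusted over the list alone. They include Il7r, the interleukin-7 receptor of early lymphocytes (0.91), and the kinase Blk (0.77). The list median was 0.56 (cameraPR adjusted p = 1.1e-43), a call lost at an adjusted p = 0.052 with an estimated correlation. By fry, which tests a list against no change and not against other genes, the adjusted p was 0.00013. All 8 granulocyte genes were down, over all genes as adjusted over the list alone, among them Padi4 (-0.37), an enzyme that citrullinates histones. Their median was -0.42 (adjusted p = 2.2e-13, but adjusted p = 0.26 with an estimated correlation). Of 9 adipocyte and lipid storage genes, 4 were up over all genes and 4 adjusted over the list alone. These were Scd1, the carbonic anhydrase Car3 (0.85), the fatty acid carrier Fabp4 (0.45) and the lipoprotein lipase Lpl (0.47). The adipocyte median was 0.12 (adjusted p = 1.2e-06, but adjusted p = 0.29 with an estimated correlation).

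In the megakaryocyte and platelet list, 2 of 8 genes were up over all genes, the platelet integrin Itga2b (0.45) and the adhesion protein Selp (0.29). With Thbs1 (0.31), 3 were up adjusted over the list alone, and Pf4 stood at 0.12. The list median was 0.14 (adjusted p = 0.0041, but adjusted p = 0.29 with an estimated correlation). The osteoblast and bone matrix list of 14 genes had a median of 0.15 (adjusted p = 0.0041, but adjusted p = 0.48 with an estimated correlation). By limma 0 of its members passed over all genes and 0 adjusted over the list alone. The smallest p were those of the collagens Col1a1 (0.46, unadjusted p = 0.0069 by limma) and Col1a2 (0.43), the collagen chaperone Serpinh1 (0.40) and Mmp2 (0.25). Oxidative phosphorylation (36 genes, median -0.06) and cytosolic ribosome (42 genes, median 0.05) passed at adjusted p = 0.035 and 0.033, but both stood at adjusted p = 0.66 with an estimated correlation. Of their members 0 passed by limma over all genes and 0 adjusted over the list alone. The smallest unadjusted p were those of the respiratory chain subunits Cox7a2 (-0.18) and Ndufa1 (-0.19) and the ribosomal proteins Rpl21 (0.15) and Rpl26 (0.15), between 0.0069 and 0.027.

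The other lists did not pass with cameraPR in this average. The osteoclast list had a median of -0.06 (adjusted p = 0.22), although Mmp9 (-0.43), a gelatinase of osteoclasts and neutrophils, and the proton pump subunit Atp6v1b2 (-0.22) were down over all genes and Src (0.18) was up adjusted over the list alone. Medians of signalling lists were -0.04 for RANKL, OPG and Wnt (adjusted p = 0.93) and 0.03 for BMP, TGF-beta and IGF (0.10). Those of cell types were -0.02 for monocytes, macrophages and dendritic cells (0.68), 0.00 for erythroid genes (0.93), 0.08 for endothelial genes (0.29) and -0.05 for skeletal muscle (0.93). Those of cell states were 0.01 for cell cycle (0.93), 0.09 for the interferon response (0.73), -0.05 for inflammatory cytokines and receptors (0.87) and -0.07 for the heat shock and immediate early response (0.10). Sex steroid receptors, metabolism and response had a median of -0.07 (0.45), with Klf9 (-0.16), Esr1 (-0.11) and Tsc22d3 (-0.15) at the smallest p. Tnfsf11, the osteoclast factor RANKL, and Igf1, the growth factor, passed by limma in no group and not in the average under either reading. Their averages under the castrated-over-sham reading were 0.02 and 0.01 for the features of Tnfsf11 and 0.02 and -0.02 for those of Igf1. Tnfrsf11b was not among the tested features.

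In all, 359 features passed in the average by limma under the castrated-over-sham reading, 179 up and 180 down, for 256 named genes. An unadjusted p under 0.05 was seen for 1441, with 444 expected by chance. Of the 359, 234 had the same sign on every array and 167 met the rule for stating a direction. Under the channel reading 0 features passed by limma, with 418 at an unadjusted p under 0.05. Its dye term held 231 features, of which 220 were among the 359, each with the same sign. The count of 359 moved by over 1.5 times without young bone replicate 3 (142), young marrow replicate 1 (177), 2 (96) or 3 (219), old replicate 2 (109) or old replicate 3 (574). It was 86 on the unswapped arrays alone. The oxidative phosphorylation call was lost without young bone replicate 1 (adjusted p = 0.12), young marrow replicate 1 (0.094) or old replicate 2 (0.48). The ribosome call was lost without young bone replicate 3 (0.19), young marrow replicate 2 (0.087) or 3 (0.075), or old replicate 1 (0.066) or 3 (0.081).

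The channel reading called a single list in the average, cell cycle (34 genes, median -0.12, adjusted p = 1e-05, but adjusted p = 0.99 with an estimated correlation). By limma 0 members passed over all genes and 0 adjusted over the list alone. The smallest p belonged to the proliferation marker Mki67 (-0.30), the spindle proteins Tacc3 (-0.24) and Kif23 (-0.19) and the replication helicase subunit Mcm4 (-0.17), at unadjusted p between 0.0027 and 0.032 by limma. The median was 0.01 under the other reading, and without young marrow replicate 2 it was -0.06 (adjusted p = 0.12). Among features, the smallest p under the channel reading, at a limma adjusted p of 0.89, were those of the immunoglobulin gene Ighg3 (-0.76), Mki67 (-0.36), Mkrn1 (-0.31), Ccser1 (0.25) and Acad8 (0.34). Ddx21 (-0.27), the actin Actg1 (0.21), Taok3 (-0.25), the protease Casp1 (-0.20) and the lactate transporter Slc16a1 (-0.23) came next. Under the castrated-over-sham reading the signs of all these features but Ddx21 were turned, with Ighg3 at 0.55 and Mki67 at 0.06.

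**Figure D1:**
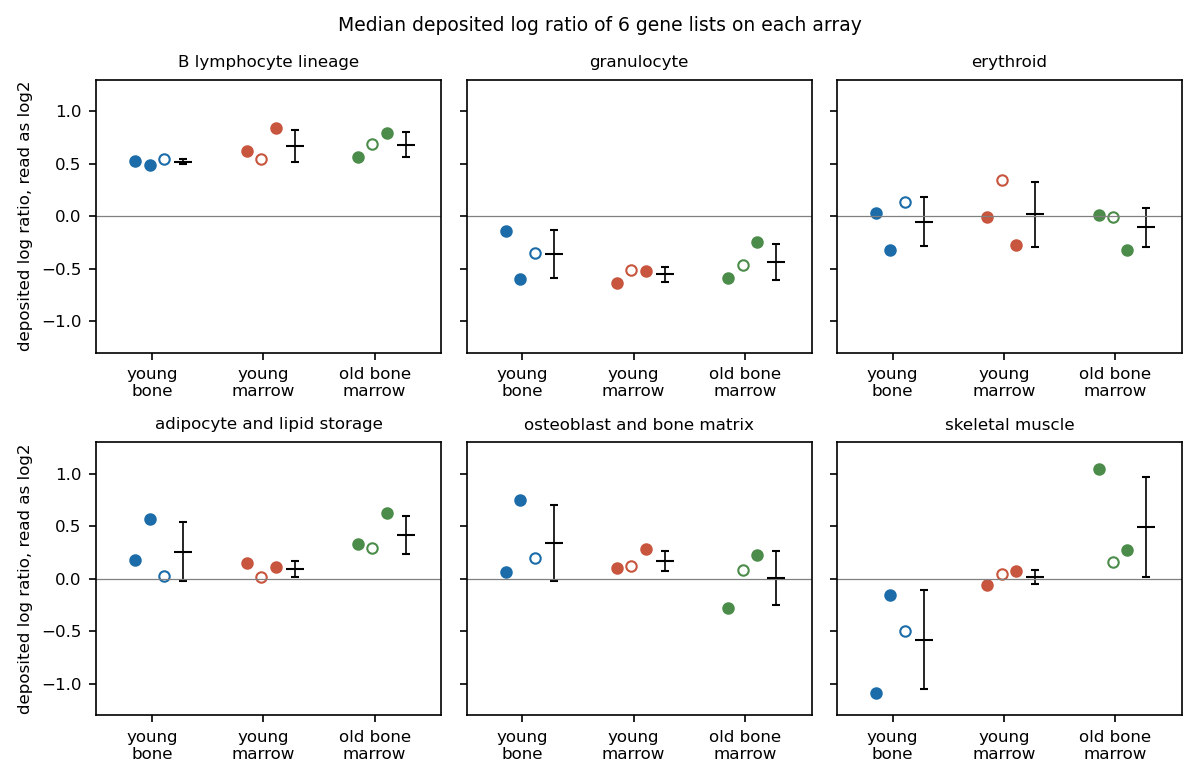
Median deposited log ratio (y axis, read as log2) of 6 gene lists on each of the 9 arrays, by group (x axis); filled points have the castrated mouse in Cy5, open points in Cy3, and black bars give the mean and SD of 3 arrays. The B lymphocyte medians lie between 0.49 and 0.84 and the granulocyte medians between -0.64 and -0.14.

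Young bone was compared to find the castration response of the bone specimens, whose content of marrow cells was not measured here. Bach2, the B cell transcription factor, rose by 1.35 (SE 0.13, n = 3 arrays, limma adjusted p = 0.0018) and 0.96 in its features under the castrated-over-sham reading. Il7r rose by 1.02 (SE 0.09), Vpreb3 by 1.01 (SE 0.10) and Cecr2, a chromatin remodelling protein, by 0.90, each positive on 3 of 3 arrays. Bcl6, a transcriptional repressor of lymphocytes, fell by 0.59 (SE 0.09, limma adjusted p = 0.020). Under the channel reading Bach2 stood at 0.29 and 0.09, Il7r at 0.08, Vpreb3 at 0.13, Cecr2 at 0.01 and Bcl6 at -0.04. With signs that differ between the readings, the deposited ratio was above 0 on 3 of 3 arrays for Fcrla (1.0), Strn3 (0.99), Igfbp5 (0.85), Scd1 (0.85) and Blk (0.80). It was below 0 on 3 of 3 for Slpi, a protease inhibitor of leukocytes (-0.81).

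Of the 12 B lymphocyte genes, 6 were up over all genes in young bone and 7 adjusted over the list alone under the castrated-over-sham reading. Their median was 0.48 (cameraPR adjusted p = 5.5e-23, but adjusted p = 0.095 with an estimated correlation). Among the 8 granulocyte genes 1 was down over all genes and 5 adjusted over the list alone, with Anxa1 (-0.50), Lyz2 (-0.61), Ctsg (-0.60) and the granule protease Prtn3 (-0.31) at the smallest p. The granulocyte median was -0.34 (adjusted p = 7.1e-07, but adjusted p = 0.31 with an estimated correlation). The bone matrix list had a median of 0.27 (adjusted p = 5.9e-05, but adjusted p = 0.43 with an estimated correlation). By limma 0 of its members passed over all genes and 0 adjusted over the list alone, and Col1a1 (0.77), Col1a2 (0.82), Serpinh1 (0.68) and Mmp2 (0.44) had unadjusted p between 0.0066 and 0.015. All 8 skeletal muscle genes were negative, with a median of -0.60 (adjusted p = 4.8e-07, but adjusted p = 0.43 with an estimated correlation). The myosin light chain Myl1 (-1.09) was down over all genes. Adjusted over the list alone 6 were down, among them the muscle enolase Eno3 (-0.74), Mylpf (-0.66) and the myoglobin Mb (-0.98). The adipocyte list had a median of 0.11 (adjusted p = 5.9e-05, but adjusted p = 0.31 with an estimated correlation), with Scd1 and Car3 (0.95), 2 genes, up over all genes. Adjusted over the list alone 4 were up, with Fabp4 (0.36) and Lpl (0.62) added. The osteoclast list did not pass (median -0.07, adjusted p = 0.39), and its Atp6v1b2 (-0.17), Mmp9 (-0.16) and Snx10 (-0.17) did not either. Without young bone replicate 2 the bone matrix call was lost (adjusted p = 0.21).

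Lists with smaller medians also passed in young bone. BMP, TGF-beta and IGF signalling had a median of 0.08 (adjusted p = 0.028, but adjusted p = 0.31 with an estimated correlation), with Igfbp5 (0.84) its 1 member up, over all genes as over the list alone. The TGF-beta receptor Tgfbr2 stood at 0.28, Igfbp4 at 0.21 and the signal transducer Smad5 at 0.20. Monocyte, macrophage and dendritic genes had a median of -0.12 (adjusted p = 0.032, but adjusted p = 0.44 with an estimated correlation). In this list the macrophage protein Mpeg1 (-0.57) was down over all genes and the chemokine receptor Ccr2 (-0.53) adjusted over the list alone, while Aif1 (-0.23) and H2-Eb1 (0.20) did not pass. Sex steroid genes had a median of -0.15 (adjusted p = 0.038, but adjusted p = 0.44 with an estimated correlation), led by the nuclear receptor coactivator Ncoa4 (-0.25), Klf9 (-0.25) and Tsc22d3 (-0.36). Oxidative phosphorylation had a median of -0.10 (adjusted p = 0.00045, but adjusted p = 0.44 with an estimated correlation), led by Cox7a2 (-0.31), Sdhb (-0.34), Ndufa9 (-0.35) and Ndufa5 (-0.37). Cytosolic ribosome had a median of 0.06 (adjusted p = 0.032, but adjusted p = 0.62 with an estimated correlation), led by Rps24 (0.33), Rpl39 (0.29), Rpl26 (0.25) and Rpl41 (0.25). In the sex steroid, oxidative phosphorylation and ribosome lists 0 members passed by limma over all genes and 0 adjusted over the list alone. Without young bone replicate 1 the adjusted p were 0.050 for BMP, 0.088 for monocytes, 0.12 for sex steroid, 0.051 for oxidative phosphorylation and 0.050 for ribosome, and each call was lost. Other calls lost were BMP (0.12), monocyte (0.11) and sex steroid (0.11) without young bone replicate 2 and sex steroid (0.055) without old replicate 2, and without young bone replicate 3 the ribosome median was -0.02 (0.60).

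In young bone 23 features passed by limma under the castrated-over-sham reading, 20 up and 3 down, for 16 named genes, with 780 at an unadjusted p under 0.05. Of the 23, 10 met the rule for stating a direction. Under the channel reading 0 passed by limma, with 606 at an unadjusted p under 0.05. The features with the smallest p there, at a limma adjusted p of 0.62, were the galactokinase Galk2 (0.69, SE 0.11), Ccdc80 (0.56), Mocs1 (0.58), the translation factor Eef1a1 (0.52) and Ighg3 (-1.27). The ribosomal protein Rpsa (-0.49), Mkrn1 (-0.62), Skp2 (-0.44), Otud6b (-0.48) and the adhesion protein Alcam (0.43) came next. The count of 23 was 6 without young bone replicate 1, 14 without replicate 2, 1 without replicate 3, 52 without old replicate 1 and 80 without old replicate 3. It was 1 on the unswapped arrays alone.

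The channel reading called bone matrix, cell cycle and interferon response in young bone, each at adjusted p = 0.79 with an estimated correlation. By limma 0 of their members passed over all genes and 0 adjusted over the list alone. The bone matrix median was 0.14 (adjusted p = 0.0095), with Col1a2 at 0.57, Col1a1 at 0.46 and the proteoglycan Lum at 0.38. The cell cycle median was -0.18 (adjusted p = 5e-05), with Kif20a at -0.39 and the replication proteins Mcm7, Mcm5 and Cdc45 at -0.44, -0.37 and -0.36. The interferon median was -0.17 (adjusted p = 0.0095), with the transcription factors Stat2 (-0.31) and Irf1 (-0.32), the GTPase Gbp2 (-0.42) and Psmb8 (-0.28). The bone matrix call was lost without young bone replicate 2 (adjusted p = 0.81) and the interferon call without young bone replicate 1 (0.18).

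Young marrow was compared to find the response of the blood-forming tissue. Igfbp5 rose by 1.24 (SE 0.10, n = 3 arrays, limma adjusted p = 0.0010), Vpreb3 by 1.12 (SE 0.10) and Pou2af1 by 1.07 (SE 0.10) under the castrated-over-sham reading. Fcrla rose by 1.14 and 0.94 in its features, Pafah1b3 by 1.05, Cd79b by 1.0, the B progenitor transcription factor Sox4 by 0.98 and Bach2 by 0.94, each positive on 3 of 3 arrays. A second feature of Igfbp5 had a deposited ratio of 1.18, above 0 on 3 of 3 arrays. The endosomal protein Rab11fip4 fell by 0.71 (SE 0.09, limma adjusted p = 0.0066), the matrix protein fibronectin, Fn1, by 0.69 and 0.67 in its features, and Mmp9 by 0.68 (SE 0.10). The actin-binding Svil fell by 0.58, with a range of -0.58 to -0.23 over its 5 features, and Padi4 fell by 0.55. The deposited ratio of Slpi was also below 0 on 3 of 3 arrays (-0.64). Under the channel reading the rises were far smaller, with Igfbp5 at 0.03, Vpreb3 at 0.14, Pou2af1 at 0.15 and the first feature of Fcrla at 0.08. Pafah1b3 stood at 0.04 there, Cd79b at 0.02, Sox4 at 0.17 and Bach2 at 0.07.

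Of the 12 B lymphocyte genes, 6 were up over all genes in young marrow and 9 adjusted over the list alone under the castrated-over-sham reading, with Il7r at 0.89. The median was 0.59 (cameraPR adjusted p = 9.2e-29, but adjusted p = 0.071 with an estimated correlation). Among the 8 granulocyte genes 3 were down over all genes and 8 adjusted over the list alone, led by Padi4, Anxa1 (-0.52), Lyz2 (-0.70) and the integrin Itgam (-0.63). The granulocyte median was -0.53 (adjusted p = 7.1e-13, but adjusted p = 0.21 with an estimated correlation). The 8 megakaryocyte and platelet genes were all positive, with a median of 0.34 (adjusted p = 3.9e-05, but adjusted p = 0.21 with an estimated correlation). Itga2b (0.73) was up over all genes. Adjusted over the list alone 5 were up, among them the platelet receptor Clec1b (0.60), Selp (0.46) and Thbs1 (0.61). Cytosolic ribosome had a median of 0.12 (adjusted p = 0.0024, but adjusted p = 0.87 with an estimated correlation), led by Rps4x (0.25), Rpl26 (0.25), Rpl12 (0.24) and Rps29 (0.19). By limma 0 ribosomal genes passed over all genes and 0 adjusted over the list alone, and the call was lost without young marrow replicate 2 (adjusted p = 0.052) or 3 (0.071).

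Other lists fixed for bone did not pass in young marrow. The bone matrix list (median 0.16, adjusted p = 0.21) held Serpinh1 (0.87), up adjusted over the list alone, with Col1a1 (0.61) and Sparc (0.58) next. In the osteoclast list (median -0.09, adjusted p = 0.094) Mmp9 passed over all genes, Atp6v1b2 (-0.27) adjusted over the list alone, and the kinase Src (0.33) did not pass. In the adipocyte list (median 0.01, adjusted p = 0.45) Scd1 (0.62) was up over all genes, and Lpl (0.44) and Fabp4 (0.23) did not pass. In the sex steroid list (median 0.04, adjusted p = 0.89) Ncoa4 (0.16), Ncoa3 (0.15) and the glucocorticoid receptor Nr3c1 (0.05) did not pass.

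In young marrow 75 features passed by limma under the castrated-over-sham reading, 65 up and 10 down, for 54 named genes, with 933 at an unadjusted p under 0.05. Of the 75, 57 met the rule for stating a direction. Under the channel reading 0 passed by limma, with 67 at an unadjusted p under 0.05, fewer than the 444 expected by chance. The smallest p there belonged, at a limma adjusted p of 1, to Cmtr1 (0.37, SE 0.10), Acad8 (0.54), Pcyox1 (0.60), ACT1 as the annotation names it (0.70, on 2 arrays) and Bcl7a (0.43). Rufy3 (0.33), Large2 (0.34), the second feature of Strn3 (0.51), the heparanase Hpse (0.38) and Sgce (0.31) came next. The count of 75 was 6 without young marrow replicate 1, 0 without replicate 2, 10 without replicate 3 and 138 without old replicate 3. It was 3 on the unswapped arrays alone.

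The channel reading called erythroid, megakaryocyte and platelet, cell cycle, and heat shock genes in young marrow, each at adjusted p = 0.77 with an estimated correlation. Of their members, 0 passed by limma over all genes and 0 adjusted over the list alone. The erythroid median over 8 genes was -0.15 (adjusted p = 0.0034), with the blood group antigen Kel at -0.32 and the haem enzyme Fech at -0.36. The megakaryocyte median was 0.13 (adjusted p = 0.0019), with Clec1b at 0.34. The cell cycle median was -0.11 (adjusted p = 7.2e-05), with Tacc3 at -0.29 and Mki67 at -0.26. The heat shock median over 21 genes was 0.06 (adjusted p = 0.0034), with the chaperones Hspa8, Dnaja1 and Hsph1 at 0.33, 0.30 and 0.39. Without young marrow replicate 2 the erythroid call was lost (adjusted p = 0.49) and the cell cycle median was 0.03. Without replicate 3 the erythroid (0.091) and megakaryocyte (0.19) calls were lost and the heat shock median was -0.03.

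**Figure D2:**
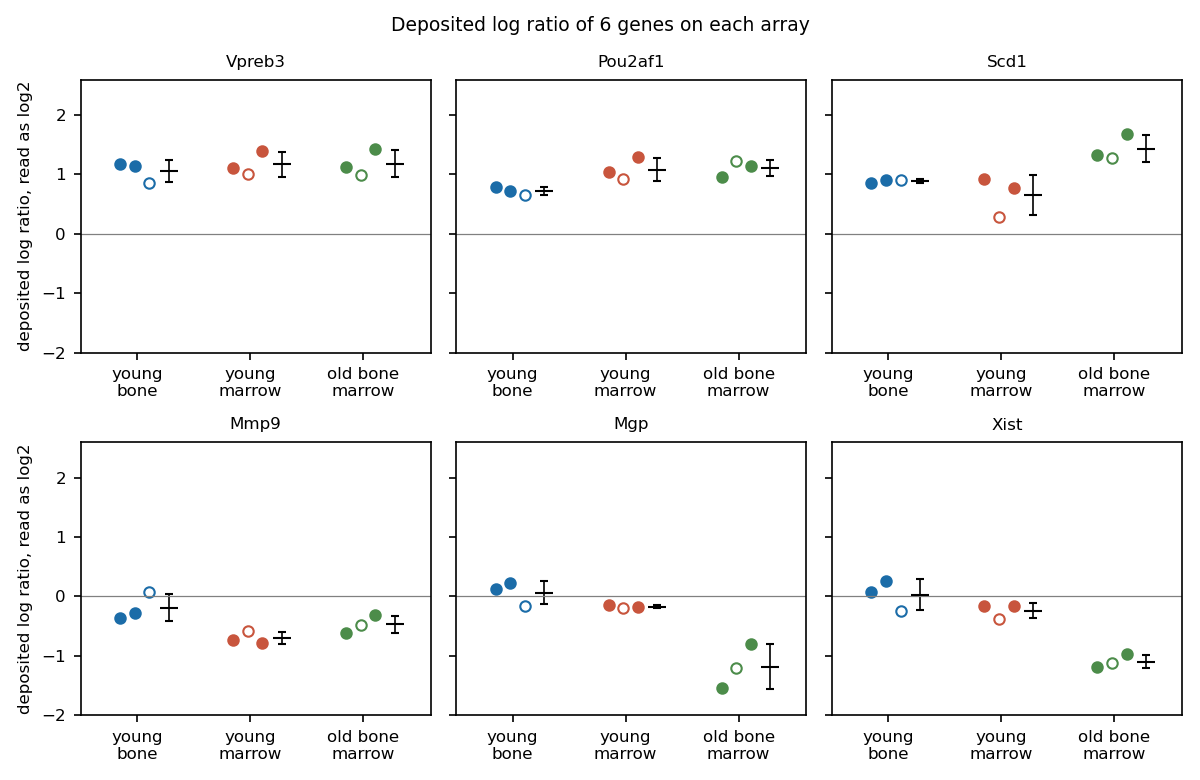
Deposited log ratio (y axis, read as log2) of 6 named genes on each of the 9 arrays, by group (x axis); filled points have the castrated mouse in Cy5, open points in Cy3, and black bars give the mean and SD of 3 arrays. Vpreb3 lies between 0.85 and 1.43 on every array, and Xist lies between -1.19 and -0.98 on the old arrays and between -0.39 and 0.26 on the young ones.

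The old group was compared to find the response at an advanced age, in mice of 59 weeks. This age goes with a longer time since castration than in the young groups. Scd1 rose by 1.39 (SE 0.11, n = 3 arrays, limma adjusted p = 0.00046) and Car3, abundant in fat and muscle, by 1.41 (SE 0.18) under the castrated-over-sham reading. Strn3 rose by 1.42 (SE 0.10, limma adjusted p = 0.00042), and the nuclear non-coding RNA Malat1 by 1.21, with 0.59 to 1.21 over its 3 features. The B cell genes Vpreb3 (1.14), Fcrla (1.10) and Cd79b (1.06) rose as well, and so did Igfbp5 (1.0). The deposited ratios of Pou2af1 (1.10) and Bach2 (1.08) were above 0 on 3 of 3 arrays. Mgp, the matrix protein that inhibits calcification, fell by 1.21 (SE 0.13, limma adjusted p = 0.0018). Xist, the RNA of X-chromosome inactivation that is normally silent in males, fell by 1.14 (SE 0.10, limma adjusted p = 0.00046).

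Smaller falls in the old group were those of Cish, a feedback inhibitor of cytokine signalling (-0.81), the immediate early gene Ier3 (-0.63) and Anxa1 (-0.63). The guanine deaminase Gda (-0.54), Rab11fip4 (-0.48) and the glyoxalase Glo1 (-0.46) also fell, with limma adjusted p for these 6 genes between 0.026 and 0.045. The deposited ratios of Cep19 (-0.65) and the transcription factor Zbtb7b (-0.54) were below 0 on 3 of 3 arrays. Of the 9 adipocyte genes 3 were up over all genes and 4 adjusted over the list alone, with Fabp4 at 0.76 and the lipogenic Thrsp at 0.43. The adipocyte median was 0.34 (cameraPR adjusted p = 2e-09, but adjusted p = 0.29 with an estimated correlation). Of the 12 B lymphocyte genes 6 were up over all genes and 9 adjusted over the list alone, with a median of 0.70 (adjusted p = 2.9e-26, but adjusted p = 0.080 with an estimated correlation). Of the 8 granulocyte genes 1 was down over all genes and 6 adjusted over the list alone, with the collagenase Mmp8 (-0.63), Padi4 (-0.41) and Lyz2 (-0.54) beside Anxa1. The granulocyte median was -0.47 (adjusted p = 4.1e-06, but adjusted p = 0.56 with an estimated correlation).

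All 8 skeletal muscle genes were positive in the old group, with a median of 0.52 (adjusted p = 0.00012, but adjusted p = 0.56 with an estimated correlation). By limma 0 passed over all genes and 3 were up adjusted over the list alone, the creatine kinase Ckm (0.81), Tpm2 (0.62) and Mylpf (0.69), with Mb at 0.68. The deposited muscle list medians were 1.04, 0.16 and 0.27 on old replicates 1, 2 and 3, so replicate 1 stood far above the others. Oxidative phosphorylation had a median of -0.16 (adjusted p = 0.0049, but adjusted p = 0.63 with an estimated correlation), led by Cox7a2 (-0.32), Ndufs4 (-0.35), Ndufa4 (-0.22) and Cox7b (-0.22). None of its members, 0 over all genes and 0 adjusted over the list alone, passed by limma. The heat shock and immediate early list had a median of -0.15 (adjusted p = 0.0067, but adjusted p = 0.62 with an estimated correlation), with Ier3 down over all genes. Adjusted over the list alone 5 were down, among them Egr1 (-0.88) and Dusp1 (-0.39), and 1 was up, Klf2 (0.37). The oxidative phosphorylation call was lost without old replicate 2 (adjusted p = 0.58), and the heat shock call without old replicate 2 (0.12) or 3 (0.13). In the bone matrix list (median 0.06, adjusted p = 0.21) Mmp13 (0.31) and Lox (-0.30) did not pass, and Col5a2 (0.43) passed adjusted over the list alone. In the osteoclast list (median -0.12, adjusted p = 0.77) Mmp9 (-0.44) passed adjusted over the list alone, and Traf6 (0.29) and Atp6v1b2 (-0.22) did not. In the sex steroid list (median -0.10, adjusted p = 0.60) Klf9 (-0.22), Esr1 (-0.15) and Nr3c1 (-0.13) did not pass.

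In the old group 65 features passed by limma under the castrated-over-sham reading, 54 up and 11 down, for 46 named genes, with 1615 at an unadjusted p under 0.05. Of the 65, 45 met the rule for stating a direction. Under the channel reading 0 passed by limma, with 203 at an unadjusted p under 0.05. The smallest p there belonged, at a limma adjusted p of 0.97, to Ppp1r10 (0.46, SE 0.10), the histone H1f3 (0.96), Thbs2 (-0.55 and -0.57), Cdc27 (-0.37) and Tmem104 (-0.65). The interleukin-2 receptor chain Il2rb (0.39), Immp1l (0.77), the ubiquitin ligase Cbl (-0.52) and Kidins220 (-0.49) came next. The count of 65 was 33 without young bone replicate 1, 43 without young bone replicate 3, and 30, 29 and 41 without young marrow replicates 1, 2 and 3. It was 10 without old replicate 2 and 1332 without old replicate 3, and 13 on the unswapped arrays alone. Old replicate 1 had an SD of 0.455 across features, the highest of the 9 arrays, and a median of -0.12 over those tested.

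The channel reading called adipocyte, skeletal muscle and oxidative phosphorylation genes in the old group, each at adjusted p = 0.95 with an estimated correlation. By limma 0 of their members passed over all genes and 0 adjusted over the list alone. The adipocyte median was 0.08 (adjusted p = 0.036), with Car3 at 0.50, Thrsp at 0.35, Fabp4 at 0.30 and Scd1 at 0.27. The muscle median was 0.33 (adjusted p = 0.00072), with Mb at 0.71, Ckm at 0.56 and Tpm2 at 0.26. The oxidative phosphorylation median was 0.06 (adjusted p = 0.015), with Ndufb9 at 0.17 and Ndufs4 at -0.21. The adipocyte call was lost without young marrow replicate 3 (adjusted p = 0.061), old replicate 1 (0.12) or 3 (0.74), and the muscle call without old replicate 1 (0.89). Without old replicate 2 the oxidative phosphorylation median was -0.06.

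The calls of the groups under the castrated-over-sham reading overlapped. Young bone and young marrow shared 17 rises and 1 fall (0.15 and 0.0034 expected), young bone and the old group 17 rises (0.12 expected), and young marrow and the old group 32 rises and 2 falls (0.40 and 0.012 expected). The expected numbers assume independent calls, while the groups share the dye term of the fit, so they are no test of the overlap. By limma 0 features passed in opposite directions. The 16 features past the threshold in all 3 groups had positive deposited ratios and named 14 genes. These were the B cell genes Bach2, Fcrla, Pou2af1, Il7r, Vpreb3, Blk and Siglecg, the lymphoid transcription factor Lef1, and Sbk1, Strn3, Igfbp5, Glcci1, Cecr2 and Scd1.

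The differences between groups ask whether age or tissue changed the response. For old minus young bone, 1 feature passed by limma under the castrated-over-sham reading, Xist, with a difference of -1.13 (SE 0.13, n = 9 arrays in the fit, adjusted p = 0.045). Its ratio was -1.14 in the old group and -0.01 in young bone, and 589 features had an unadjusted p under 0.05. Without old replicate 3 the count was 31, and without any 1 of the other 8 arrays it was 0, with Xist no longer past the threshold. Under the channel reading 0 passed by limma, with 363 at an unadjusted p under 0.05. The skeletal muscle list stood higher in the old group by a median of 1.09 (adjusted p = 9.5e-18, but adjusted p = 0.56 with an estimated correlation). By limma 0 of its genes passed over all genes and 6 adjusted over the list alone. The channel reading gave a muscle median of 0.49 (adjusted p = 0.0032, but adjusted p = 0.74 with an estimated correlation).

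For old minus young marrow, 0 features passed by limma under the castrated-over-sham reading, with 1292 at an unadjusted p under 0.05, and 0 under the channel reading, with 67. The adipocyte list stood higher in the old group by a median of 0.45 (adjusted p = 5.6e-05, but adjusted p = 0.73 with an estimated correlation), with 4 of 9 genes up adjusted over the list alone. The differences were 0.77 for Scd1, 1.21 for Car3 and 0.53 for Fabp4, each at a limma adjusted p of 0.343 over all features. Without old replicate 3 the count over all features was 885. For young bone minus young marrow, 0 features passed by limma under the castrated-over-sham reading, with 455 at an unadjusted p under 0.05, and 0 under the channel reading, with 148. The megakaryocyte and platelet list stood lower in bone by a median of -0.32 under both readings, at adjusted p = 0.00083 and 0.00062, but adjusted p = 0.49 and 0.75 with an estimated correlation. Adjusted over the list alone 1 of its genes passed under the castrated-over-sham reading and 0 under the channel reading, and 0 over all genes by limma. Over all features and in the main analysis of either reading, Xist alone passed a test of a difference. Other genes past the threshold in a single group are not shown by it to differ between groups.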

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

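The tests of cell type, adhering muscle and sex given in this part were all chosen after the results had been seen, while the splits of the arrays were planned.

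Differences between groups were picked up where the test of the difference itself passed, for whole gene lists or for single features. All list calls below come from cameraPR with a preset correlation. With an estimated correlation the adjusted p of these calls lay between 0.49 and 0.87, so none passed there. By fry, which tests a list against no change, they lay between 0.33 and 0.85. Values are medians of the differences between groups in the castration effect.

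For young bone minus young marrow, the channel reading gave -0.32 for megakaryocytes and platelets (adjusted p = 0.00062), -0.23 for the interferon response (0.0026) and -0.10 for heat shock (0.029). On the castrated-over-sham reading the values were -0.63 for skeletal muscle (3.5e-05), -0.32 for megakaryocytes and platelets (0.00083) and -0.14 for oxidative phosphorylation (3.5e-05). Granulocyte genes had 0.17 (0.029), adipocyte genes 0.13 (0.029) and sex steroid genes -0.19 (0.034).

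For old minus young marrow, the channel reading gave 0.32 for skeletal muscle (adjusted p = 0.0089). On the castrated-over-sham reading the values were 0.45 for adipocyte genes (5.6e-05), 0.40 for skeletal muscle (0.00098) and -0.21 for oxidative phosphorylation (0.00098). Cell cycle had -0.24 (0.015), heat shock -0.23 (0.015) and cytosolic ribosome -0.16 (0.027). The cell cycle, oxidative phosphorylation and ribosome signs were turned on the channel reading (0.05, 0.08 and 0.01).

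For old minus young bone, the channel reading gave 0.49 for skeletal muscle (adjusted p = 0.0032), 0.25 for the interferon response (0.00082) and -0.22 for bone matrix (0.032). It also gave 0.15 for cell cycle (0.0052) and 0.09 for oxidative phosphorylation (0.032), whose signs were turned on the castrated-over-sham reading (-0.11 and -0.05). The castrated-over-sham reading gave 1.09 for skeletal muscle (9.5e-18), 0.17 for monocytes (0.014), 0.02 for adipocyte genes (0.029) and 0.08 for B lymphocyte genes (0.048). Of single features, Xist passed with -1.13.

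Whether chance can be excluded was asked by turning the signs of arrays, or by splitting the 6 arrays of 2 groups in other ways. For the average on the castrated-over-sham reading, 1 of 100 drawn sign patterns, the real one, gave as many features (359, against 8 at most in the others). Chance can be excluded there if the 9 arrays are independent, which is not stated for young bone and young marrow. For the average on the channel reading the real count was 0, which any pattern reaches by construction (100 of 100), so that the patterns say nothing about chance there. The highest other pattern gave 868, which points to a structure of the samples: it turned the 3 swapped arrays and old replicate 1. As the dye term was kept, what all arrays share went into that term. The average then set the young groups against the old arrays, with old replicate 1 weighing most. The 868 therefore do not speak for the castrated-over-sham reading.

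Single groups have 4 sign patterns and differences 10 splits, too few for a share under 0.05. On the channel reading the real count was 0 in each of these 6 comparisons and the highest other was 0, so that by construction 4 of 4 patterns and 10 of 10 splits gave as many. On the castrated-over-sham reading the real counts were 23 in young bone (1 of 4 patterns as large, highest other 0), 75 in young marrow (1 of 4, highest other 0) and 65 in the old group (2 of 4). The pattern with old replicate 3 turned gave 264, which points to a structure of these samples. Of the differences, old minus young bone had 1 feature (1 of 10 splits, highest other 0) and young bone minus young marrow 0 (10 of 10, highest other 0). Old minus young marrow had 0 (10 of 10), and another split gave 365, which again points to a structure of the samples.

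The first pattern weighed is the positive B lymphocyte and negative granulocyte medians on all 9 deposited arrays. A dye effect of single sequences, unrelated to cell type, is argued against: with the dye coefficients permuted over the genes, in 0 of 10000 permutations did any of the 19 lists reach a median as large as that of the B lymphocyte list (0.56) or the granulocyte list (-0.42). The permutations were not matched on brightness, so a dye effect that follows brightness stays open. A lower share of granulocyte RNA that raises every other cell type alike would leave the other lists level. The B lymphocyte median stood above those of the erythroid, megakaryocyte and monocyte lists by 0.67 (SD 0.30), 0.45 (SD 0.14) and 0.66 (SD 0.14), on 9 of 9 arrays. The exact sign-flip p was 0.0039 each, the smallest that 9 arrays can give. So these lists were not level, but the test cannot decide on the explanation. It takes the arrays as independent, and the B lymphocyte list was picked for lying above 0 on all 9, a choice the p is not adjusted for. If the ratios are castrated over sham, which is not settled, castration may raise the share or the expression of early B cells; this is a hypothesis, and cell counts that would tell these apart were not used here.

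The second pattern is the muscle list, below 0 on the young bone arrays (-1.09, -0.16 and -0.50) and above 0 on the old arrays (1.04, 0.16 and 0.27). Differing amounts of adhering muscle in the young bone and old specimens may account for it, although whether the old ones hold bone is not stated: the young marrow medians lay within 0.07 of 0, nearer than any bone or old array (0.16). On old replicate 1 Mb had 1.70 and Ckm 1.56, and on young bone replicate 1 Mb had -1.69 and Myl1 -1.43; their abundance was not analysed here, nor which of the 8 genes bone or marrow cells express. An opposite response of muscle to castration in young and old mice cannot be told apart from this, since both would set the young bone and old arrays apart; the exact permutation p of 3 against 3 arrays, 0.10, is the smallest such a design can give and decides nothing. Age, the time since castration and tissue as sources of the difference stay open, untested.

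The third pattern is Xist, which was low in the deposited ratios of the old arrays (-1.19, -1.13 and -0.98). A dye effect common to all arrays is argued against by the 6 young arrays. Their mean was -0.11 (SD 0.23), against -1.10 (SD 0.11) in the old group. Under the channel reading, the same sign on the swapped and unswapped old arrays would have to come from the dye. The Xist values thus argue against that reading for this gene in the old group, unless the dye acted on the old arrays alone. Mgp had the same pattern (-1.55, -1.21 and -0.80 on the old arrays, -0.20 to 0.22 on the young ones). Both genes were picked after the results were seen, so this does not settle the reading for other genes. Female mice in place of the sham-operated mice of the old pairs stay open. The median of 3 Y-linked genes was 0.16 at its highest among the old arrays. Uty stood above 0 on all 3 old arrays (1.01, 0.37 and 0.16), while Eif2s3y (-0.23, 0.02 and -0.10) and Kdm5d (-0.18, 0.07 and 0.28) did not. The Uty ratio of 1.01 came from old replicate 1, the array with the highest SD across features, and on the young arrays Uty ranged from -0.39 to 0.40. Whether these genes were detected above background is unknown, since intensities were not used here. A response of Xist that depends on age, the time since castration or tissue was not tested apart from it.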

How the results depend on the processing

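Tests of alternatives on the channel reading were planned, while all alternatives combined with the castrated-over-sham reading, and the replicate block as a fixed term, were chosen after seeing the data. Counts are features past the threshold by limma, and where a count moved, the cause was not tested unless stated.

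On the channel reading the main counts were 0 in all 7 comparisons, with 606, 67, 203 and 418 at an unadjusted p under 0.05 for young bone, young marrow, the old group and the average, and 148, 67 and 363 for young bone minus young marrow, old minus young marrow and old minus young bone. Taking the castrated-over-sham reading gave 23 in young bone, 75 in young marrow, 65 in the old group, 359 in the average and 1 in old minus young bone. These counts differ by construction through the sign of the swapped arrays. With only the unswapped arrays and no dye term, where both readings are identical, the counts were 1, 3, 13 and 86 for the groups and the average. Array weights gave 2 and trend and robust moderation 1 in old minus young bone. Leaving out each array gave a range of 0 to 0 in all 7 comparisons.

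On the castrated-over-sham reading the counts were 0 under the channel reading for the 3 groups, the average and old minus young bone. Young bone, 23 in the main analysis, gave 50 without the dye term, 1 on the unswapped arrays alone, 1 with array medians set to 0 and equal spread, 76 with array weights, 36 at gene level and 3 when fitted alone without a dye term. Young marrow, 75, gave 3 on the unswapped arrays alone, 160 with medians 0 and equal spread, 1551 with array weights, 42 with trend and robust moderation and 207 fitted alone. The old group, 65, gave 13, 14, 328, 33 and 9 under the same 5 settings. The average, 359, gave 86 on the unswapped arrays alone, 1056 with array weights and 220 with trend and robust moderation. As that trend follows the mean log ratio, its counts do not show the effect of a spread that depends on intensity. On the unswapped arrays fewer samples are tested, by construction.

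Differences on the castrated-over-sham reading moved too. Young bone minus young marrow, 0 in the main analysis, gave 5 with array weights. Old minus young marrow, 0, gave 3 with medians 0 and equal spread, 2 on features with a value on all 9 arrays, 481 with array weights and 1 at gene level. Old minus young bone, 1, gave 2 with array weights or at gene level, and 0 without the dye term, on the unswapped arrays alone, with trend and robust moderation or when the 2 groups were fitted alone. The average has no version fitted alone.

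Setting the array medians to 0, where old replicate 1 had a median of -0.12, gave 27, 83, 85 and 379 for young bone, young marrow, the old group and the average. The balance of the average changed with this, to 226 up and 153 down against 179 and 180, and it was 63 and 23 on the unswapped arrays alone and 73 and 23 without young marrow replicate 2. With equal spread as well, young marrow had 102 up and 58 down, against 65 and 10, and young bone 0 up and 1 down. With array weights young marrow had 808 up and 743 down, the old group 188 and 140 against 54 and 11, and the average 477 and 579.

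Leaving out each array gave ranges of 1 to 80 in young bone, 0 to 138 in young marrow, 10 to 1332 in the old group and 96 to 574 in the average. The lowest were without young bone replicate 3, young marrow replicate 2, old replicate 2 and young marrow replicate 2, and the highest without old replicate 3 each time. The differences ranged from 0 to 0 for young bone minus young marrow, 0 to 885 for old minus young marrow and 0 to 31 for old minus young bone.

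A replicate block was also fitted, although the labels do not say that equal numbers in bone and marrow are the same mice. Young bone and young marrow arrays of equal number did not correlate best, which does not show that the mice differ. Its consensus correlation was -0.042 on the castrated-over-sham reading, with counts of 23, 74, 65 and 371 for young bone, young marrow, the old group and the average, and 0.105 on the channel reading. As a fixed term, the replicate block gave 7 features in young bone minus young marrow, where the main count was 0. That fit rests on 3 differences within replicate number and also holds a dye term, which leaves few residual degrees of freedom before moderation. It used only features with a value in all 3 differences.

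List calls with cameraPR depend on the preset correlation: with an estimated correlation 27 of 27 calls on the castrated-over-sham reading and 11 of 11 on the channel reading no longer passed. By fry, which asks whether a list differs from no change and not from other genes, 10 of the 27 and 0 of the 11 passed. Without the dye term 26 and 9 passed with the same sign, with array medians set to 0 26 and 10.

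List medians that changed sign from the channel to the castrated-over-sham reading were erythroid (0.07) and cell cycle (0.09) in young marrow, oxidative phosphorylation in the old group (-0.16) and cell cycle in the average (0.01). In the other direction, channel reading values were -0.03 for B lymphocytes, 0.06 for granulocytes and -0.05 for ribosome in young bone and -0.01 for ribosome in young marrow. They were 0.06 for oxidative phosphorylation and 0.02 for heat shock in the old group. In the average they were 0.01 for granulocytes, -0.05 for megakaryocytes, 0.01 for oxidative phosphorylation and -0.02 for ribosome. With an array left out, signs turned on the channel reading for cell cycle in young marrow (range -0.19 to 0.03, highest without young marrow replicate 2) and heat shock in young marrow (-0.03 to 0.17, lowest without young marrow replicate 3). They also turned for oxidative phosphorylation in the old group (-0.06 to 0.13, lowest without old replicate 2) and, on the castrated-over-sham reading, for ribosome in young bone (-0.02 to 0.09, lowest without young bone replicate 3).

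Named genes on the castrated-over-sham reading gave 70 calls, of which 67 passed with the same sign without the dye term. On the channel reading 49 no longer passed, with the same sign or a value of 0.00 as printed, and 21 turned. In young bone these were Fcrla (-0.17), Strn3 (-0.14), Igfbp5 (-0.07), Scd1 (-0.03), Blk (-0.04) and Slpi (0.25). In young marrow it was Slpi (0.23), and in the old group Pou2af1 (-0.02), Bach2 (-0.19), Cep19 (0.01) and Zbtb7b (0.02). In the average they were Fcrla (-0.02), Strn3 (-0.02), Cd79b (-0.05), Pafah1b3 (-0.02), Il1r2 (0.02), Lyz2 (0.01), Arg2 (0.11), Dmxl2 (0.03) and Ctsg (0.03 in both features). With each array left out in turn, 475 of 630 results passed with the same sign and 155 no longer passed.

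Signal over background cannot be given, since intensities were not used here, so what it limits is unknown.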

Other observations

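The values in this part were picked after they had been seen, and no tests were added for them. Fn1, the matrix protein fibronectin, fell in young marrow, and its features gave 0.33 and 0.29 in young bone on the castrated-over-sham reading. The difference of 1.02 between young bone and young marrow (SE 0.16) had a limma adjusted p of 0.174, so it did not pass. Correlations between arrays across features, as deposited, ranged from -0.30 to 0.56, with 30 of 36 pairs above 0.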
